A study of Mus musculus with 16 samples.

How the data were processed

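RNA was measured in 16 bulk sequencing libraries from the small intestine of untreated Tph1-CFP mice, in which cyan fluorescent protein marks enterochromaffin (EC) cells, the serotonin-producing endocrine cells of the gut epithelium. Crypt and villus fractions were dissociated and sorted by fluorescence into EC cells (CFP-positive) and other epithelial cells (CFP-negative, here epi), with 5000 cells pooled per library. The 4 groups were crypt EC, crypt epi, villus EC and villus epi, with 4 libraries each. Libraries were full-length cDNA amplified from very small amounts of RNA. The design text gives 4 mice or samples per group, so the labels do not say which number is a mouse. Replicate numbers here are those of the sample titles, and the library numbers in the labels differ from them.

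The deposited table holds gene-level values named FPKM (fragments per kilobase of transcript, scaled to the fragments of the library). The authors' processing notes list bcl2fastq 2.20, kallisto and sleuth with mouse genome build mm10, and how each library was scaled and which annotation release was used are not given in the sources used here. Column totals ran from 731415 to 1415120, so the values are not shares of a fixed total, and some further scaling between libraries cannot be ruled out. Read counts were not used here, so the depth of each library is unknown and no counting interval or detection floor is given. The table has 20072 genes, each above 0 in at least 2 libraries. A GENCODE gene annotation for mm10 gave positions for 19944 of them by Ensembl identifier, 84 had no symbol, and 22 symbols occurred more than once.

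Values were used as deposited, with 1 added before taking log2. Genes with a value of at least 1 in at least 4 of the 16 libraries were tested, which kept 14089 genes and left out 5983. Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a trend of the variance on the mean), in 1 fit of all 16 libraries with 4 group means and no replicate block. The tests were two-sided, p values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p below 0.05. The 5 contrasts were EC against epi in the crypt, EC against epi in the villus, villus against crypt in EC, villus against crypt in epi, and the interaction of cell type and site. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Group values in the text are means of the deposited values ± SD over 4 libraries, and fold changes are differences of mean log2 values, so the ratio of 2 printed means need not equal the fold.

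A total of 37 gene lists was fixed before the data were examined. They cover serotonin synthesis and storage, secretory granules, exocytosis, endocrine transcription factors, gut hormones, somatostatin receptors, other G protein-coupled receptors, Gi and Go signalling, ion channels, cell adhesion, lipid, carbohydrate and peptide absorption, xenobiotic metabolism, villus tip and villus bottom genes, stem cells, the cell cycle, and the Wnt, Notch and BMP pathways. They also cover Paneth, goblet and tuft cells, lymphocytes, myeloid cells, stroma, neurons and glia, red blood cells, stress genes, ribosomal proteins, mitochondrial transcripts, oxidative phosphorylation, cholesterol, MHC class II, interferon-stimulated genes and the unfolded protein response. Each list was tested with camera (limma, preset correlation between genes of 0.01), adjusted over the lists of a contrast. The same test with an estimated correlation, and fry, were alternatives. The number of members called was also counted with p values adjusted over the list alone. Members neither higher nor lower were not called, and the median of a list is that of the log2 fold changes of its tested members.

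The rule for named genes, also fixed before then, took the 10 genes with the largest positive and the 10 with the largest negative log2 fold change per contrast, among called genes with a mean of at least 5 in the higher group and no overlap between the libraries of both groups, leaving out unnamed gene models. The interaction took 8 and 8, with no criterion on overlap. The rule added up to 4 called members of each list with the largest change, and about 30 genes whatever their values, among them Tph1, the hormone genes and Sstr1 to Sstr5. The text names a part of these genes in each comparison, picked after the results were seen, and a few are not reported here. Sstr4 has no entry in the table, and Piezo2 and Adra2a did not pass the filter.

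The method was tested on simulated data made from the spread of the deposited values, with 200 genes changed. It recovered 43% and 44% of genes changed by 1 log2 unit in the crypt and villus contrasts of EC and epi, and 89% and 85.5% of those changed by 2. Of calls in these contrasts, 1.15% to 9.28% were false. Contrasts without simulated change had 0 or 1 gene called. Camera called the 1 list shifted by 1 log2 unit and 0 others, with correlated genes untested.

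The alternatives were pseudocounts of 0.1 and 5, no filter, a filter on a mean of at least 5, median-ratio scaling, the 8 libraries of the groups compared alone, no variance trend, library weights, replicate blocks by title or library number, and leaving out each library. Leaving out villus epi replicate 2 together with median-ratio scaling, and leaving out each library for the lists, were added after the data were seen. GC content and length were those of the longest annotated transcript of each gene.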

Results

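The series profiled RNA from sorted EC cells and from the other epithelial cells of the crypt and the villus of mouse small intestine, with 4 libraries in each of 4 groups. Its title names the regulation of EC cells by somatostatin, and its design asks which genes differ between EC and other epithelial cells at both sites. Deposited values summed to 748830 ± 15020.3 (SD, n = 4) per library in crypt EC, 1091070.0 ± 38276 in crypt epi, 864600.0 ± 42073 in villus EC and 1346850.0 ± 104716 in villus epi. The depth behind these values is unknown. Between 11318 and 13071 genes per library had a value of 1 or more. The most abundant transcript was Reg4 in the crypt EC libraries, Defa24 in the crypt epi libraries, and Sct in 3 of the 4 villus EC libraries.

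The first principal component took 50.8% of the variance and separated EC from epi, and the second took 26.3%. The third took 10.8% and set villus epi replicate 2 apart from every other library. That library had a mean correlation across genes of 0.812 with its own group, where the other villus epi libraries reached 0.923 to 0.926 and the other groups 0.971 to 0.985. Genes are not independent replicates in these correlations. Mitochondrially encoded transcripts took 3.38% ± 0.642 (SD, n = 4) of the total in crypt EC, 3.68% ± 0.354 in crypt epi, 2.34% ± 0.121 in villus EC and 10.8% ± 4.03 in villus epi.

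In the crypt, EC cells differed from other epithelial cells first by the genes of serotonin and peptide secretion. Tph1, the rate-limiting enzyme of peripheral serotonin synthesis, was at 5392 ± 1175 in crypt EC against 1.57 ± 0.563 in crypt epi (SD, n = 4, log2 fold change 11.04 ± 0.30 (SE), adjusted p = 6.02e-13). The chromogranin genes Chga (16042 ± 591 against 11.3 ± 2.11) and Chgb (29622 ± 1555 against 53.3 ± 17.9) rose by 10.36 and 9.16 log2 units (adjusted p = 6.72e-15 and 9.75e-14). Tac1, which encodes substance P, rose by 9.22, and Ucn3, which encodes urocortin 3, rose by 9.28 (734 against 0.165, adjusted p = 6.72e-15). Goblet cell markers were among the genes with a large fall, such as Clca1 (23.2 ± 21.2 against 3134 ± 459, log2 fold change -7.65, adjusted p = 4.84e-06), Zg16 (-7.23) and the mucin gene Muc2 (-6.25).

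On mm10, Tph1 (ENSMUSG00000040046, chromosome 7, 46644641 to 46672537) and Chga (ENSMUSG00000021194, chromosome 12, 102554969 to 102565028) are among the genes with the largest rise, and Clca1 (ENSMUSG00000028255, chromosome 3, 145003817 to 145032776) is among those with the largest fall. Other genes with a large rise were Afp (10.27), which encodes alpha-fetoprotein, Amigo2 (8.62), Igfbp2 (252 against 0.0664, log2 fold change 7.87) and the transcription factor Lmx1a (7.90). The genes above had adjusted p values between 6.72e-15 and 5.57e-06. For serotonin synthesis and storage, 8 of 13 tested were higher and 3 lower (8 and 3 adjusted over the list alone, median log2 fold change 2.20, camera adjusted p = 0.00383, adjusted p = 0.173 with an estimated correlation). Its members include the monoamine transporters Slc18a1 (825 against 17.6, log2 fold change 5.47) and Slc18a2 (112 against 2.37, 5.06), and the decarboxylase Ddc (3.59).

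Among secretory granule proteins and prohormone processing enzymes, 13 of 16 tested were higher and 0 lower (13 and 0 adjusted over the list alone, median 4.77, camera adjusted p = 3.38e-12). For regulated exocytosis, 23 of 27 tested were higher and 1 lower (24 and 1 adjusted over the list alone, median 3.04, camera adjusted p = 8.01e-14). Members include Snap25 at 6.87 and Rab3c at 7.88. For enteroendocrine transcription factors, 16 of 20 tested were higher and 1 lower (18 and 1 adjusted over the list alone, median 2.69, camera adjusted p = 7.13e-11). In this list, Neurod1 was at 5.96 and Nkx2-2 at 5.55. For Gi and Go signalling components, 15 of 22 tested were higher and 1 lower (16 and 1 adjusted over the list alone, median 1.53, camera adjusted p = 1.64e-06). Of its genes, the Go subunit gene Gnao1 was at 4.64. For ion channels, 25 of 40 tested were higher and 4 lower (26 and 4 adjusted over the list alone, median 1.23, camera adjusted p = 1.17e-08). Among them, the irritant receptor gene Trpa1 went from 0.0732 to 233 (log2 fold change 7.77, adjusted p = 2.2e-14) and the sodium channel gene Scn3a rose by 6.46. For cell adhesion and synaptic surface proteins, 7 of 10 tested were higher and 1 lower (7 and 1 adjusted over the list alone, median 1.46, camera adjusted p = 0.00164, adjusted p = 0.173 with an estimated correlation). Within it, Cntnap2 was at 3.25.

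All 4 tested somatostatin receptor genes were higher in crypt EC. The receptor gene Sstr1 (ENSMUSG00000035431, chromosome 12, 58211772 to 58214444) had 172 ± 30.1 in crypt EC against 0.611 ± 0.379 in crypt epi (SD, n = 4, log2 fold change 6.76 ± 0.31 (SE), adjusted p = 1.52e-10). For Sstr5 (ENSMUSG00000050824, chromosome 17, 25489875 to 25497288) the values were 45.2 ± 5.71 and 1.23 ± 0.319 (log2 fold change 4.38, adjusted p = 3.02e-09). Lower were Sstr2 (ENSMUSG00000047904, chromosome 11, 113619342 to 113626028) (7.78 ± 0.826 and 1.42 ± 0.475, log2 fold change 1.88, adjusted p = 1.02e-05) and Sstr3 (ENSMUSG00000044933, chromosome 15, 78537008 to 78544685) (4.39 ± 0.711 and 0.744 ± 0.258, log2 fold change 1.63, adjusted p = 2.64e-06). As a list, 4 of 4 tested were higher and 0 lower (4 and 0 adjusted over the list alone, median 3.13, camera adjusted p = 0.000266, adjusted p = 0.0879 with an estimated correlation). For other G protein-coupled receptors of enteroendocrine cells, 11 of 22 tested were higher and 6 lower (12 and 6 adjusted over the list alone, median 0.70, camera adjusted p = 0.16), with Glp1r (4.22) and the fatty acid receptor gene Ffar2 (3.84) among those that rose.

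Hormone genes went both ways. In the list of gut peptide hormones, 6 of 16 tested were higher and 4 lower (6 and 5 adjusted over the list alone, median 0.69, camera adjusted p = 0.404). Sct, which encodes secretin, rose by 4.30 (adjusted p = 1.06e-05). The hormone genes of other endocrine types fell in crypt EC, with Gip at 13.3 against 1434 (-6.82), Sst at 1.40 against 176 (-6.64), Gcg at 8.90 against 249 (-6.49) and Pyy at -2.72 (adjusted p between 1.44e-06 and 0.000922). Cck did not pass the test (log2 fold change -0.69, adjusted p = 0.551). Crypt EC replicate 1 held most of the Gcg and Sst of its group.

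Markers of the other epithelial types were lower in crypt EC. For goblet cells, 0 of 17 tested were higher and 17 lower (0 and 17 adjusted over the list alone, median -5.26, camera adjusted p = 6.28e-14). For Paneth cells, 1 of 17 tested were higher and 15 lower (1 and 15 adjusted over the list alone, median -4.63, camera adjusted p = 4.56e-12). Members include the lysozyme gene Lyz1 at 1851 against 49583 (log2 fold change -4.77, adjusted p = 1.3e-09) and Itln1 at -4.83. The 10 Paneth markers with at least 1000 in crypt epi stood in crypt EC at a median of 3.80% of that level. For tuft cells, 1 of 18 tested were higher and 11 lower (1 and 11 adjusted over the list alone, median -1.25, camera adjusted p = 0.000889, adjusted p = 0.358 with an estimated correlation). In this list, Dclk1 was at -2.62 and Rgs13 at -3.34. For villus bottom antimicrobial genes, 1 of 10 tested were higher and 9 lower (1 and 9 adjusted over the list alone, median -2.71, camera adjusted p = 2.6e-05, adjusted p = 0.103 with an estimated correlation). Of its genes, Reg3g was at -4.81. Defa, Reg3 and Clca genes belong to families of near-identical members, so the split of reads among members is uncertain.

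Proliferation and metabolism genes fell too. For the cell cycle, 0 of 29 tested were higher and 28 lower (0 and 29 adjusted over the list alone, median -1.60, camera adjusted p = 3.38e-12, adjusted p = 0.0683 with an estimated correlation). Within it, Ccnb2 was at -2.17, Cdc20 at -2.08 and Mki67 at -1.82. For lipid absorption, 1 of 18 tested were higher and 13 lower (1 and 13 adjusted over the list alone, median -1.99, camera adjusted p = 2.65e-06, adjusted p = 0.279 with an estimated correlation). Members include the fatty acid binding protein gene Fabp1 at -4.07. For nuclear oxidative phosphorylation genes, 1 of 36 tested were higher and 33 lower (1 and 34 adjusted over the list alone, median -0.97, camera adjusted p = 3.38e-12, adjusted p = 0.0841 with an estimated correlation). In this list, Uqcrfs1 was at -1.45 and Cyc1 at -1.36.

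Some genes of non-epithelial lists were high in crypt EC. C1qa, a complement gene, was at 125 against 0.165 (log2 fold change 6.76, adjusted p = 8.36e-15), yet of the B, plasma and myeloid cell markers 1 of 8 tested were higher and 2 lower (1 and 2 adjusted over the list alone, median -0.21, camera adjusted p = 0.985). The median of that list is negative and its mean is 0.42, and the test fry gave the opposite direction to camera. The intermediate filament gene Vim (160.3 against 2.46, log2 fold change 5.54, adjusted p = 5.53e-11) belongs to the stromal and endothelial markers, of which 2 of 7 tested were higher and 0 lower (2 and 0 adjusted over the list alone, median 0.46, camera adjusted p = 0.213). Of the T and intraepithelial lymphocyte markers, 0 of 6 tested were higher and 1 lower (0 and 0 adjusted over the list alone, median -0.08, camera adjusted p = 0.65), and Ptprc, which encodes CD45, did not pass the test (log2 fold change -0.12, adjusted p = 0.896). For enteric neuron and glia markers, 5 of 7 tested were higher and 0 lower (5 and 0 adjusted over the list alone, median 1.29, camera adjusted p = 0.00882, adjusted p = 0.0628 with an estimated correlation). Of its genes, Ret was at 3.47 and Tubb3 at 2.23. For erythroid markers, 4 of 5 tested were higher and 0 lower (4 and 0 adjusted over the list alone, median 2.26, camera adjusted p = 0.108), and that list was called without crypt epi replicate 4 (adjusted p = 0.0345). The hemoglobin genes that make up most of it are near-identical.

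With limma and Benjamini-Hochberg adjustment, 3264 of 14089 genes were higher and 2824 lower in crypt EC, and 1976 and 1493 of these changed at least 2-fold. Without villus epi replicate 2, which enters only through the shared estimate of the spread, the counts were 4726 and 4294. Camera calls held with an estimated correlation for secretory granules (adjusted p = 0.017), exocytosis (0.00032), transcription factors (0.012), Gi and Go signalling (0.0322), ion channels (0.0054), Paneth (0.0054) and goblet markers (0.017). With a pseudocount of 5, 9 of 55 named called genes and 6 of 20 called lists moved by over 1.5 times and kept their calls, such as Sstr3 (0.71), Sstr2 (0.99), Glp1r (2.62), and the medians of ion channels (0.41), cell adhesion (0.48) and neuron and glia markers (0.41). With 0.1, 3 genes and 6 lists did, and these medians were 2.57, 3.29 and 3.02.

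**Figure D1:**
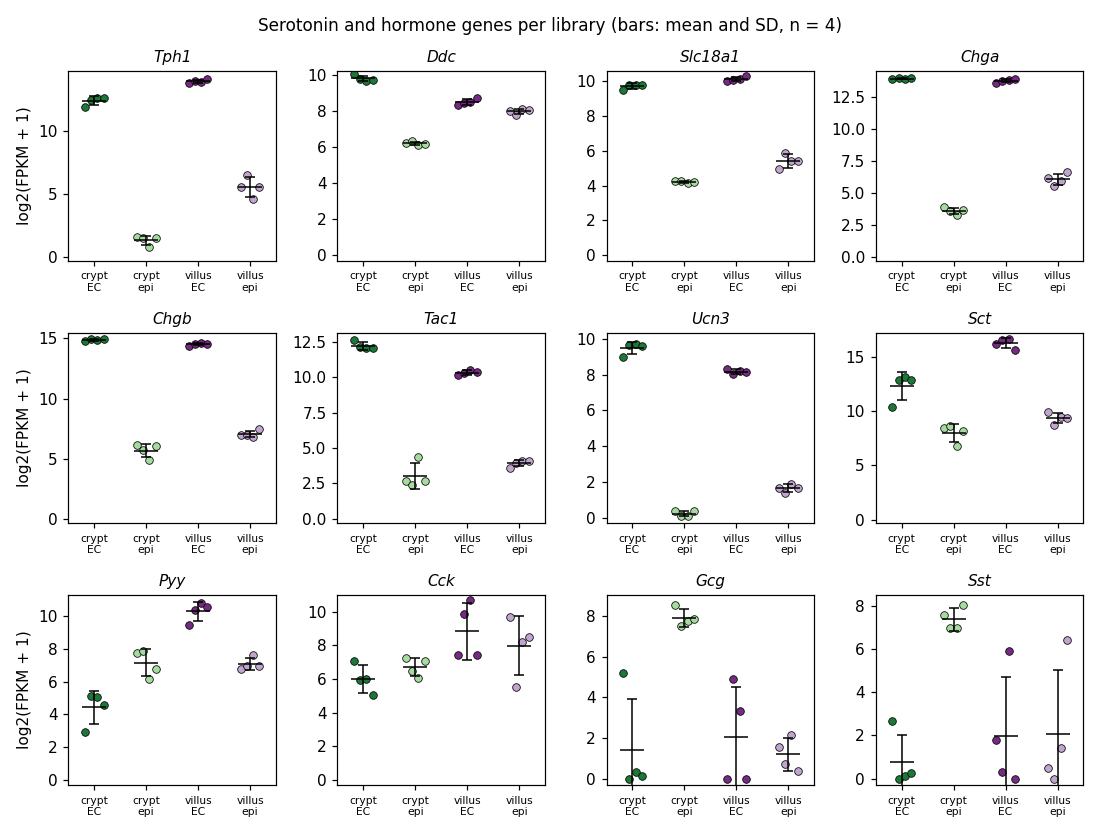
Each panel plots log2(FPKM + 1) of 1 gene in the 16 libraries by group, with the mean and SD of 4 libraries as bars. Tph1, Chga, Chgb, Tac1 and Ucn3 lie higher in every EC library than in every epi library of the same site, while Cck, Gcg and Sst vary between libraries of a group.

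In the villus, Tph1 was again far higher in EC cells than in other epithelial cells. It was at 15282 ± 1469 in villus EC against 50.3 ± 26.8 in villus epi (SD, n = 4, log2 fold change 8.36 ± 0.30 (SE), adjusted p = 5.7e-12). Afp rose by 9.73, Reg4 by 8.78 (44849 against 99.8), Chga by 7.74 and Chgb by 7.44. The largest falls included Mbl2, which encodes a mannose-binding lectin (0.308 ± 0.218 against 425 ± 178, log2 fold change -8.23, adjusted p = 4.91e-12), the alkaline phosphatase gene Alpi (-7.94) and H2-Aa (-7.90).

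On mm10, Reg4 (ENSMUSG00000027876, chromosome 3, 98222156 to 98236748) and Mbl2 (ENSMUSG00000024863, chromosome 19, 30232942 to 30239687) were among the genes with the largest rise and fall. Gpx3 (8.35), Ambp (8.48) and Glp1r (7.79) were also among the genes with the largest rise, and Slc18a1 rose by 4.69. The monoamine oxidase gene Maoa was lower in villus EC, at 8.76 against 467 (-5.43), as was the serotonin transporter gene Slc6a4 at 4.66 against 213 (-5.20). Ddc was at 366 against 254 (log2 fold change 0.52, adjusted p = 0.000632), and with median-ratio scaling its difference was 0.19 and not called (adjusted p = 0.114). For serotonin synthesis and storage, 7 of 13 tested were higher and 4 lower, with Maoa and Slc6a4 among the 4 (7 and 4 adjusted over the list alone, median 0.52, camera adjusted p = 0.65). For secretory granules, 15 of 16 tested were higher and 0 lower (15 and 0 adjusted over the list alone, median 5.32, camera adjusted p = 7.06e-08, adjusted p = 0.0744 with an estimated correlation). For regulated exocytosis, 26 of 27 tested were higher and 1 lower (26 and 1 adjusted over the list alone, median 3.71, camera adjusted p = 4.32e-10). Within it, Snap25 was at 7.41 and Syt13 at 6.57. For ion channels, 23 of 40 tested were higher and 2 lower (24 and 2 adjusted over the list alone, median 1.19, camera adjusted p = 0.000256, adjusted p = 0.0744 with an estimated correlation). Members include Trpm2 at 7.31 and Trpa1 at 6.40.

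The 4 tested somatostatin receptor genes were higher in villus EC as well, and 4 of 4 tested were higher and 0 lower (4 and 0 adjusted over the list alone, median 4.73, camera adjusted p = 0.00531, adjusted p = 0.181 with an estimated correlation). Sstr1 was at 274 ± 23.6 against 2.10 ± 1.33 (SD, n = 4, log2 fold change 6.61, adjusted p = 8.06e-11), Sstr5 at 96.4 ± 8.46 against 1.06 ± 1.05 (5.69) and Sstr2 at 23.1 ± 6.41 against 0.756 ± 0.452 (3.78). Sstr3 was low in both groups, at 1.84 ± 0.704 and 0.101 ± 0.0981 (log2 fold change 1.34, adjusted p = 9.56e-06).

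Gut peptide hormone genes were mostly higher, and 9 of 16 tested were higher and 1 lower (9 and 1 adjusted over the list alone, median 2.35, camera adjusted p = 0.0439, adjusted p = 0.281 with an estimated correlation). That call ended without villus EC replicate 3 (adjusted p = 0.097) or villus epi replicate 2 (0.144), and with a pseudocount of 0.1 (0.0627). Sct was at 79618 ± 23458 against 673 ± 219 (SD, n = 4, log2 fold change 6.89, adjusted p = 2.35e-08), Ucn3 rose by 6.52, Tac1 by 6.42 and Pyy by 3.21 (adjusted p = 2.62e-05). Gcg (log2 fold change 0.85, adjusted p = 0.549), Cck (log2 fold change 0.86, adjusted p = 0.39) and Sst (log2 fold change -0.09, adjusted p = 0.961) did not pass the test.

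Absorptive functions were lower in villus EC than in villus epi. For lipid absorption, 1 of 18 tested were higher and 17 lower (1 and 17 adjusted over the list alone, median -5.27, camera adjusted p = 8.14e-11, adjusted p = 0.16 with an estimated correlation). In this list, Apoa4 was at -7.20 and Fabp1 at -6.93. For carbohydrate digestion and sugar transport, 0 of 11 tested were higher and 10 lower (0 and 10 adjusted over the list alone, median -5.95, camera adjusted p = 3.5e-08, adjusted p = 0.16 with an estimated correlation). Of its genes, the lactase gene Lct was at -7.37 and the glucose transporter gene Slc5a1 at -7.33. For peptide digestion and amino acid transport, 0 of 17 tested were higher and 16 lower (0 and 16 adjusted over the list alone, median -5.66, camera adjusted p = 6.1e-10, adjusted p = 0.16 with an estimated correlation). For xenobiotic and retinoid metabolism, 2 of 23 tested were higher and 21 lower (2 and 21 adjusted over the list alone, median -4.31, camera adjusted p = 3.7e-10, adjusted p = 0.16 with an estimated correlation). Within it, Cyp3a25 was at -7.86. For MHC class II presentation, 0 of 7 tested were higher and 7 lower (0 and 7 adjusted over the list alone, median -5.58, camera adjusted p = 8.75e-06, adjusted p = 0.166 with an estimated correlation). Members include Cd74 at 28.4 against 4902 (-7.73). For interferon-stimulated genes, 1 of 18 tested were higher and 14 lower (1 and 15 adjusted over the list alone, median -1.27, camera adjusted p = 8.28e-07). In this list, Isg15 was at -4.24 and Ifit1 at -3.53. Muc2 fell by 4.89 (adjusted p = 2.98e-06), and Lyz1 did not pass the test (log2 fold change -0.14, adjusted p = 0.674).

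Housekeeping groups differed in the villus too. For cytosolic ribosomal proteins, 39 of 40 tested were higher and 0 lower (39 and 0 adjusted over the list alone, median 1.52, camera adjusted p = 8.95e-09, adjusted p = 0.197 with an estimated correlation). Of its genes, Rpl3 was at 58.9 against 5.69 (3.19) and Rpl13 at 2.32. For mitochondrially encoded transcripts, 0 of 13 tested were higher and 13 lower (0 and 13 adjusted over the list alone, median -2.68, camera adjusted p = 2.19e-09, adjusted p = 0.16 with an estimated correlation). Within it, mt-Co1 was at -3.26 and mt-Nd4 at -2.89. For nuclear oxidative phosphorylation genes, 0 of 36 tested were higher and 36 lower (0 and 36 adjusted over the list alone, median -1.26, camera adjusted p = 3.45e-16, adjusted p = 0.0744 with an estimated correlation). Members include Uqcrfs1 at -2.29. For cholesterol biosynthesis, 16 of 20 tested were higher and 2 lower (16 and 2 adjusted over the list alone, median 1.48, camera adjusted p = 0.0177, adjusted p = 0.253 with an estimated correlation). In this list, Sqle was at 3.11. For immediate early and heat shock genes, 15 of 20 tested were higher and 0 lower (15 and 0 adjusted over the list alone, median 2.06, camera adjusted p = 0.00185, adjusted p = 0.281 with an estimated correlation). Of its genes, Egr1 was at 4.14 and Nr4a1 at 4.44. For the unfolded protein response, 12 of 20 tested were higher and 1 lower (12 and 1 adjusted over the list alone, median 1.03, camera adjusted p = 0.0604). Within it, Pdia6 was at 2.22, and the list was called when any of 3 libraries was left out (adjusted p between 0.0269 and 0.0466 without crypt EC replicate 1, villus EC replicate 1 or villus epi replicate 3). Mitochondrially encoded transcripts took 5.26% of the total in villus epi replicate 2 and 10.9% to 14.9% in the other villus epi libraries.

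By limma with Benjamini-Hochberg adjustment, 5724 genes were higher and 3046 lower in villus EC, of which 4026 and 2132 changed at least 2-fold. Leaving out villus epi replicate 2, the counts were 6762 and 3756, and 8585 calls were shared. The median log2 fold change of all genes was 0.33 as deposited and 0.07 with median-ratio scaling, which moved the higher share of calls from 65.3% to 54.7%. Camera calls held with an estimated correlation for exocytosis (adjusted p = 0.00175) and interferon-stimulated genes (0.0472). With a pseudocount of 5, 3 of 45 named called genes and 3 of 16 called lists moved by over 1.5 times, such as ion channels (0.44), and without villus epi replicate 2 and with median-ratio scaling the median of interferon-stimulated genes was -2.02.

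The EC differences of crypt and villus overlapped. Of the genes higher in crypt EC, 2459 were also higher in villus EC, where independence would give 1326, and 171 were lower. Of the genes lower in crypt EC, 1502 were also lower in villus EC against 611 under independence, and 543 were higher. Across genes, which are not independent, the log2 fold changes had a Pearson r of 0.632 and a Spearman rho of 0.519.

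**Figure D2:**
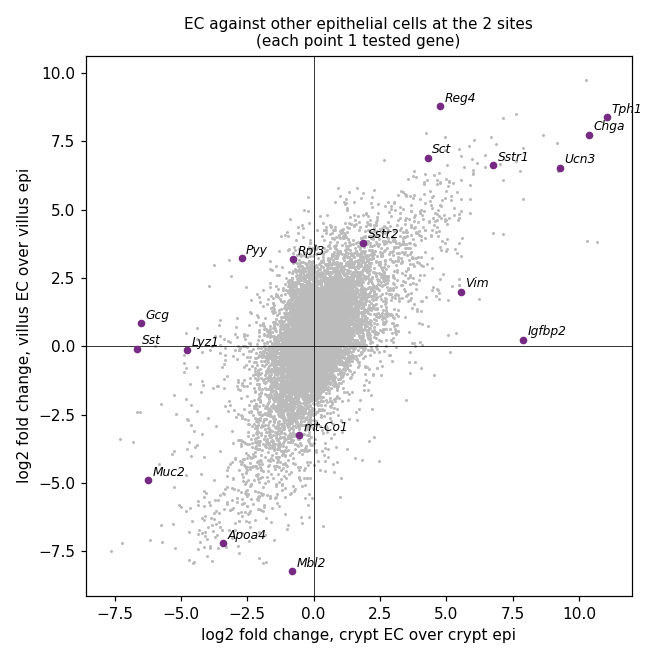
Each point is 1 tested gene, with its log2 fold change of EC over epi in the crypt on the x axis and in the villus on the y axis. Tph1 (11.04 and 8.36) and Chga (10.36 and 7.74) lie high on both axes, Igfbp2 on the x axis alone, Pyy (-2.72 and 3.21) in the upper left, and Mbl2 is low only on the y axis.

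**Figure D3:**
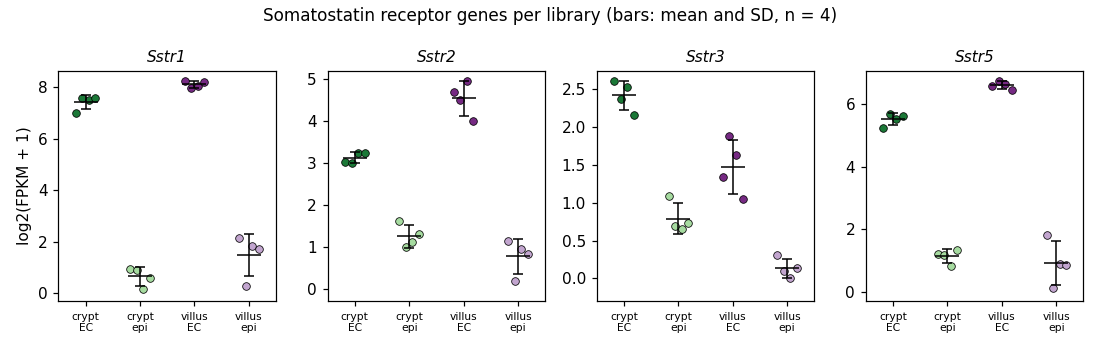
Each panel plots log2(FPKM + 1) of 1 somatostatin receptor gene in the 16 libraries by group, with the mean and SD of 4 libraries as bars. EC libraries lie above epi libraries for Sstr1, Sstr2 and Sstr5 at both sites, and Sstr3 is low in all groups.

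Between villus and crypt, EC cells differed in some hormone genes and in Slc18a2 and Ddc. Pyy, which encodes peptide YY, was at 1313 ± 458 in villus EC against 23.8 ± 12.3 in crypt EC (SD, n = 4, log2 fold change 5.86 ± 0.48 (SE), adjusted p = 2.95e-07), and Sct at 79618 ± 23458 against 6262 ± 3437 (log2 fold change 3.94, adjusted p = 5.88e-05). Tac1 (1309.6 against 4891, -1.89) and Ucn3 (286 against 734, -1.33) were lower in the villus. Tph1 rose by 1.53 (adjusted p = 0.00142) while Slc18a2, a vesicular monoamine transporter gene, went from 112 ± 11.9 to 6.21 ± 2.42 (log2 fold change -4.02, adjusted p = 1.54e-05) and Ddc fell (-1.30). The receptor gene Glp1r rose from 36.9 to 367 (3.76).

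On mm10 the genes are Pyy (ENSMUSG00000017311, chromosome 11, 102106676 to 102107832), Sct (ENSMUSG00000038580, chromosome 7, 141278330 to 141279133), Slc18a2 (ENSMUSG00000025094, chromosome 19, 59260896 to 59296012), Tac1 (ENSMUSG00000061762, chromosome 6, 7554879 to 7565834) and Ucn3 (ENSMUSG00000044988, chromosome 13, 3940688 to 3945349). Chga (log2 fold change -0.17, adjusted p = 0.605), Chgb (log2 fold change -0.35, adjusted p = 0.292) and Slc18a1 (log2 fold change 0.41, adjusted p = 0.07) did not pass the test, though Slc18a1 did without villus epi replicate 1 (adjusted p = 0.0225) or 2 (0.00567, or 0.00131 with median-ratio scaling too), with a pseudocount of 5 (0.0496), with only the 2 groups compared (0.00786) and with library weights (0.0013). For serotonin synthesis and storage, 1 of 13 tested were higher and 6 lower (3 and 6 adjusted over the list alone, median -0.54, camera adjusted p = 0.227). For secretory granules, 8 of 16 tested were higher and 1 lower (8 and 2 adjusted over the list alone, median 0.59, camera adjusted p = 0.0127, adjusted p = 0.469 with an estimated correlation). Members include Scg2 at 2.85 and Scg3 at 1.25. For gut peptide hormones, 7 of 16 tested were higher and 3 lower (7 and 3 adjusted over the list alone, median 1.28, camera adjusted p = 0.0495, adjusted p = 0.469 with an estimated correlation). That list lost its call without any 1 of 8 libraries (adjusted p between 0.0507 and 0.146), with a pseudocount of 5 (0.0641) and with median-ratio scaling (0.0844), and its median was 0.40 without villus EC replicate 3. Cartpt rose by 2.48, and Cck by 2.83 (adjusted p = 0.0204), which was not called without crypt EC replicate 4, villus EC replicate 2 or villus EC replicate 3 (adjusted p between 0.0632 and 0.0757). Gcg (log2 fold change 0.64, adjusted p = 0.776) and Sst (log2 fold change 1.24, adjusted p = 0.596) did not pass the test.

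Somatostatin receptor genes differed by site within EC cells. Sstr2 was at 23.1 ± 6.41 in villus EC against 7.78 ± 0.826 in crypt EC (SD, n = 4, log2 fold change 1.42, adjusted p = 0.000321) and Sstr5 rose by 1.08 (adjusted p = 0.00661). Sstr3 was lower in the villus (log2 fold change -0.95, adjusted p = 0.000999). Sstr1, the most abundant of them, did not pass the test (log2 fold change 0.68, adjusted p = 0.132), but it was called without villus epi replicate 2 (adjusted p = 0.00411, or 0.00192 with median-ratio scaling too), with a pseudocount of 5 (0.00343), with only the 2 groups compared (0.0019) and with library weights (0.00269). Sstr5 was not called with a pseudocount of 0.1 (adjusted p = 0.186). As a list, 2 of 4 tested were higher and 1 lower (3 and 1 adjusted over the list alone, median 0.88, camera adjusted p = 0.249).

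Genes of the crypt base and of proliferation were lower in villus EC. For intestinal stem cell markers, 1 of 18 tested were higher and 11 lower (1 and 12 adjusted over the list alone, median -1.54, camera adjusted p = 9.07e-09). In this list, Olfm4 was at 2.43 against 961 (log2 fold change -8.11, adjusted p = 6.78e-14), Smoc2 at -6.50 and Lgr5 at -3.10. For the cell cycle, 0 of 29 tested were higher and 27 lower (0 and 27 adjusted over the list alone, median -2.95, camera adjusted p = 1.29e-22). Of its genes, Cdc20 was at -4.04 and Mki67 at -1.59. For Wnt targets, 0 of 13 tested were higher and 10 lower (0 and 11 adjusted over the list alone, median -2.24, camera adjusted p = 4.8e-09). Within it, Sox9 was at -4.89 and Myc at -3.35. For Notch pathway genes, 3 of 12 tested were higher and 3 lower (3 and 3 adjusted over the list alone, median 0.11, camera adjusted p = 0.668). Members include Atoh1 at 1.88, and the median and mean (-0.06) of that list differ in sign. Neurog3, the transcription factor of endocrine progenitors, fell from 8.25 to 0.0148 (-3.15), while Neurod1 rose by 1.56. For BMP pathway genes, 7 of 14 tested were higher and 1 lower (7 and 1 adjusted over the list alone, median 0.55, camera adjusted p = 0.0198, adjusted p = 0.0937 with an estimated correlation). In this list, Id1 was at 1.86, Id3 at 1.91 and Smad6 at 2.60, and without villus epi replicate 2 that list was not called (adjusted p = 0.0527).

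Paneth markers, which may be carry-over in crypt EC, fell too, with 2 of 17 tested higher and 12 lower (3 and 12 adjusted over the list alone, median -5.17, camera adjusted p = 1.05e-10). Defa24 went from 3178 to 1.77 (-10.14), Itln1 fell by 8.09 and Lyz1 by 5.17. Defa20 was at 0 in villus EC and has no fold. Ctse (128 against 3.07, log2 fold change 5.10) and Fcgbp (3.38) were among the largest rises. For villus tip markers, 6 of 12 tested were higher and 1 lower (6 and 1 adjusted over the list alone, median 0.83, camera adjusted p = 0.00694, adjusted p = 0.427 with an estimated correlation). Of its genes, Enpp3 was at 2.99, Nt5e at 2.80 and Apoa4 at 2.25. Trpm2 rose by 2.14 and Ret by 2.28. Vim fell from 160.3 to 14.4 (-3.44) and C1qa from 125 to 19.3 (-2.63). For cytosolic ribosomal proteins, 0 of 40 tested were higher and 33 lower (0 and 37 adjusted over the list alone, median -0.72, camera adjusted p = 1.4e-11, adjusted p = 0.302 with an estimated correlation). Within it, Rps19 was at -1.49 and Rplp1 at -1.47. For mitochondrially encoded transcripts, 0 of 13 tested were higher and 0 lower (0 and 0 adjusted over the list alone, median -0.18, camera adjusted p = 0.858).

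The limma test with Benjamini-Hochberg adjustment called 1454 genes higher and 2282 lower in villus EC than in crypt EC, and 738 and 1169 changed at least 2-fold. Without villus epi replicate 2, again through the shared estimate of the spread, the counts were 2708 and 3857. Camera calls held with an estimated correlation for stem cell markers (adjusted p = 0.0174), Wnt targets (0.0174), Paneth markers (0.0174) and the cell cycle (0.0206). With a pseudocount of 5, 8 of 46 named called genes moved by over 1.5 times and kept their calls, such as Mki67 (-0.54) and Neurog3 (-1.38), and so did 5 of 11 called lists, such as Wnt targets (-1.07), the cell cycle (-1.64) and stem cell markers (-0.91). With 0.1, 2 genes and 1 list did.

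Among the other epithelial cells, the villus stood above the crypt in absorption and far below it in crypt cell types. Apoc3, an apolipoprotein gene, was at 12927 ± 2752 in villus epi against 183 ± 66.7 in crypt epi (SD, n = 4, log2 fold change 6.21 ± 0.31 (SE), adjusted p = 2.77e-10). Mbl2 (425 against 1.33, 7.39), Ly6m (7.44), Clca4a (6.64) and Cyp3a11 (6.42) also had a large rise. Lyz1 went from 49583 ± 2449 in the crypt to 55.4 ± 11.6 in the villus (log2 fold change -9.80, adjusted p = 5.77e-13). Defa17 (-10.19), Ang4 (-9.95) and Mptx2 (-9.79), other Paneth cell genes, fell by a similar amount.

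On mm10 the genes at the ends of this comparison include Apoc3 (ENSMUSG00000032081, chromosome 9, 46232933 to 46235636), Lyz1 (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868) and Olfm4 (ENSMUSG00000022026, chromosome 14, 79984081 to 80023139). For lipid absorption, 18 of 18 tested were higher and 0 lower (18 and 0 adjusted over the list alone, median 2.87, camera adjusted p = 5.51e-11, adjusted p = 0.19 with an estimated correlation). Members include Apoa4 at 6.03 and Apoa1 at 5.02. For carbohydrate digestion and sugar transport, 11 of 11 tested were higher and 0 lower (11 and 0 adjusted over the list alone, median 3.03, camera adjusted p = 1.19e-06, adjusted p = 0.226 with an estimated correlation). In this list, Lct was at 4.26. For peptide digestion and amino acid transport, 14 of 17 tested were higher and 1 lower (15 and 1 adjusted over the list alone, median 2.50, camera adjusted p = 8.04e-07, adjusted p = 0.256 with an estimated correlation). Of its genes, the peptide transporter gene Slc15a1 was at 4.92. Outside that list, the selenoprotein gene Selenop rose by 6.04. For villus tip markers, 10 of 12 tested were higher and 0 lower (10 and 0 adjusted over the list alone, median 3.87, camera adjusted p = 2.05e-07, adjusted p = 0.0615 with an estimated correlation). Within it, Ada was at 5.94. Alpi, not in that list, rose by 3.43 (adjusted p = 0.00032). For xenobiotic and retinoid metabolism, 18 of 23 tested were higher and 0 lower (18 and 0 adjusted over the list alone, median 1.80, camera adjusted p = 2.35e-09, adjusted p = 0.19 with an estimated correlation). Members include Cyp3a25 at 4.78.

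Immune-related groups were higher in villus epi. For MHC class II presentation, 7 of 7 tested were higher and 0 lower (7 and 0 adjusted over the list alone, median 2.13, camera adjusted p = 7e-04, adjusted p = 0.283 with an estimated correlation). In this list, H2-Ab1 was at 6398 against 447 (3.89) and Cd74 at 2.69 (adjusted p = 0.00327). Crypt epi replicate 3 stood above its group in both. For interferon-stimulated genes, 14 of 18 tested were higher and 2 lower (14 and 2 adjusted over the list alone, median 1.61, camera adjusted p = 3.54e-07). Of its genes, Ifit1 was at 4.16 and Isg15 at 3.57.

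Crypt cell types were lower in villus epi. For stem cell markers, 0 of 18 tested were higher and 17 lower (0 and 17 adjusted over the list alone, median -3.17, camera adjusted p = 1.01e-08). Within it, Olfm4 was at -8.21 and Smoc2 at -6.49. For the cell cycle, 0 of 29 tested were higher and 29 lower (0 and 29 adjusted over the list alone, median -4.25, camera adjusted p = 1.16e-15, adjusted p = 0.0615 with an estimated correlation). Members include Cdc20 at -6.36 and Mki67 at -3.30. For Wnt targets, 0 of 13 tested were higher and 11 lower (0 and 11 adjusted over the list alone, median -2.34, camera adjusted p = 0.000279, adjusted p = 0.124 with an estimated correlation). In this list, Myc was at -4.57, Sox9 at -4.30 and Lgr5 at -3.51. For Paneth markers, 0 of 17 tested were higher and 17 lower (0 and 17 adjusted over the list alone, median -8.90, camera adjusted p = 2.67e-12). For goblet markers, 0 of 17 tested were higher and 13 lower (0 and 13 adjusted over the list alone, median -2.23, camera adjusted p = 0.000644, adjusted p = 0.266 with an estimated correlation). Of its genes, Spink4 was at -3.70 and Muc2 at -2.22 (adjusted p = 0.00481). The Muc2 value was -1.35 without villus epi replicate 2.

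Ribosomal and mitochondrial transcripts moved in opposite directions. For cytosolic ribosomal proteins, 0 of 40 tested were higher and 40 lower (0 and 40 adjusted over the list alone, median -2.61, camera adjusted p = 5.31e-19, adjusted p = 0.0914 with an estimated correlation). Within it, Rpl3 was at 5.69 ± 1.57 against 190.3 ± 8.38 (SD, n = 4, log2 fold change -4.87), Rps19 at -4.53 and Rpl13 at -4.31. For mitochondrially encoded transcripts, 13 of 13 tested were higher and 0 lower (13 and 0 adjusted over the list alone, median 2.03, camera adjusted p = 1.52e-08, adjusted p = 0.188 with an estimated correlation). Members include mt-Co1 at 21833 ± 5043 against 3364 ± 195 (2.67) and mt-Nd3 at 2.81. Villus epi replicate 2 had the lowest mitochondrial share of its group. For cholesterol biosynthesis, 2 of 20 tested were higher and 15 lower (2 and 15 adjusted over the list alone, median -1.82, camera adjusted p = 0.00131, adjusted p = 0.19 with an estimated correlation). In this list, Fdft1 was at -3.02. For the unfolded protein response, 2 of 20 tested were higher and 13 lower (2 and 13 adjusted over the list alone, median -1.45, camera adjusted p = 0.00597, adjusted p = 0.367 with an estimated correlation). Of its genes, Pdia6 was at -3.52 and Ern2 at -3.35.

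Some EC transcripts in the sorted-negative cells were higher in villus epi. Tph1 was at 50.3 ± 26.8 against 1.57 ± 0.563 (SD, n = 4, log2 fold change 4.20, adjusted p = 1.42e-08), Chga rose by 2.46, Chgb by 1.38, Slc18a1 by 1.19 and Ddc by 1.76. For serotonin synthesis and storage, 6 of 13 tested were higher and 3 lower (7 and 3 adjusted over the list alone, median 0.86, camera adjusted p = 0.0299, adjusted p = 0.283 with an estimated correlation), and that call ended without villus epi replicate 4 (adjusted p = 0.0511). For secretory granules, 5 of 16 tested were higher and 1 lower (4 and 1 adjusted over the list alone, median 0.32, camera adjusted p = 0.0704), a list called with a pseudocount of 0.1 (0.0382) and without crypt epi replicate 1 (0.0362). For enteroendocrine transcription factors, 2 of 20 tested were higher and 6 lower (2 and 6 adjusted over the list alone, median -0.31, camera adjusted p = 0.675). For gut peptide hormones, 3 of 16 tested were higher and 4 lower (2 and 3 adjusted over the list alone, median 0.11, camera adjusted p = 0.608), and the median and mean (-0.76) of that list differ in sign. Cartpt, a member of it, was listed at 0 in crypt epi. Gcg went from 249 in crypt epi to 1.61 in villus epi (log2 fold change -6.70, adjusted p = 0.000148) and Sst fell (log2 fold change -5.31, adjusted p = 0.00364), while Pyy did not pass the test (log2 fold change -0.07, adjusted p = 0.914).

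With limma and Benjamini-Hochberg adjustment, 2761 genes were higher and 4994 lower in villus epi, and 1760 and 3513 changed at least 2-fold. Without villus epi replicate 2 the counts were 3627 and 5831, and 7531 calls were shared. The median log2 fold change of all genes was -0.19 as deposited and 0.08 with median-ratio scaling, which moved the higher share of calls from 35.6% to 50.2%. Camera calls held with an estimated correlation for Paneth markers (adjusted p = 0.0134), stem cell markers (0.0196) and interferon-stimulated genes (0.0249). Without villus epi replicate 2 and with median-ratio scaling, the medians were -0.85 for the unfolded protein response, -1.16 for cholesterol and 1.39 for serotonin genes, and Muc2 was at -0.98. With a pseudocount of 5, that of Wnt targets was -1.02 and Mki67 was at -1.62. Site differences of EC and epi overlapped, with 488 genes higher in both (285 under independence) and 1415 lower in both (809 under independence), and 312 and 278 of the genes higher and lower in villus EC went the other way in epi. Across genes, which are not independent, the 2 sets of log2 fold changes had a Pearson r of 0.396 and a Spearman rho of 0.343.

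The interaction compares the EC difference of the villus with that of the crypt, so a positive value means a larger EC excess, or a smaller EC deficit, in the villus. Pyy (log2 fold change 5.93 ± 0.67 (SE), adjusted p = 5.35e-06), Gcg (log2 fold change 7.34, adjusted p = 0.00207) and Sst (log2 fold change 6.55, adjusted p = 0.0122) had positive values. In the crypt these were at 23.8, 8.90 and 1.40 in EC against 157, 249 and 176 in epi. Sct was also positive (log2 fold change 2.59, adjusted p = 0.013), while Cck did not pass the test (log2 fold change 1.55, adjusted p = 0.317). Negative values were those of Tph1 at log2 fold change -2.67 ± 0.43 (SE), adjusted p = 0.000142, Ddc at -3.06, Slc18a2 at -4.66, Chga at -2.62, Chgb at -1.72, Tac1 at -2.80 and Ucn3 at -2.76. Within EC cells Tph1 was higher in the villus and Chga did not pass the test, and the epi levels of both were 50.3 and 68.4 in the villus against 1.57 and 11.3 in the crypt.

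For secretory granules, 5 of 16 tested were higher and 3 lower (6 and 3 adjusted over the list alone, median 0.39, camera adjusted p = 0.967), so Chga and Chgb do not stand for that list. For serotonin synthesis and storage, 3 of 13 tested were higher and 9 lower (3 and 9 adjusted over the list alone, median -1.60, camera adjusted p = 0.00274, adjusted p = 0.238 with an estimated correlation), and Slc18a1 was at -0.78 (adjusted p = 0.0101). Among somatostatin receptor genes, Sstr2 (log2 fold change 1.90 ± 0.33 (SE), adjusted p = 0.000296) and Sstr5 (log2 fold change 1.31, adjusted p = 0.0106) had a larger EC excess in the villus, and Sstr1 (log2 fold change -0.15, adjusted p = 0.813) and Sstr3 (log2 fold change -0.29, adjusted p = 0.389) did not pass the test. Sstr5 was not called with a pseudocount of 0.1 (adjusted p = 0.0777), Sstr3 was called with one of 5 (0.0359), and Sstr1 (-0.71) without villus epi replicate 2 and with median-ratio scaling (0.0243). In the list 2 of 4 tested were higher and 0 lower (2 and 0 adjusted over the list alone, median 0.58, camera adjusted p = 0.664). Glp1r was at 3.57.

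Igfbp2 and Mbl2 had large negative values. On mm10, Igfbp2 (ENSMUSG00000039323, chromosome 1, 72824503 to 72852474) was at 252 ± 47.0 in crypt EC and 0.576 ± 0.113 in villus EC (SD, n = 4), with 0.0664 in crypt epi and 0.349 in villus epi (interaction -7.63 ± 0.24 (SE), adjusted p = 3.56e-11), and Mbl2 had an interaction of -7.40. Vim was at -3.56. The secretory genes Habp2 (6.75), Agr2 (6.37) and Clps (6.18) had positive values, with Agr2 at 814 in crypt EC, 6479.9 in crypt epi, 5039 in villus EC and 565 in villus epi. For Paneth markers, 14 of 17 tested were higher and 1 lower (14 and 1 adjusted over the list alone, median 3.62, camera adjusted p = 7.83e-06, adjusted p = 0.15 with an estimated correlation). Within it, Lyz1 was at 4.63. For goblet markers, 10 of 17 tested were higher and 1 lower (11 and 1 adjusted over the list alone, median 2.93, camera adjusted p = 0.00243, adjusted p = 0.301 with an estimated correlation). For the cell cycle, 23 of 29 tested were higher and 0 lower (25 and 0 adjusted over the list alone, median 1.61, camera adjusted p = 8.39e-07, adjusted p = 0.238 with an estimated correlation). Members include Plk1 at 4.05 and Mki67 at 1.70. Olfm4 did not pass the test (log2 fold change 0.10, adjusted p = 0.753).

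Absorptive and metabolic groups differed between sites in their EC contrast. For lipid absorption, 0 of 18 tested were higher and 15 lower (0 and 15 adjusted over the list alone, median -2.64, camera adjusted p = 4.36e-09, adjusted p = 0.238 with an estimated correlation). In this list, Apoc3 was at -5.23 and Apoa4 at -3.78. For carbohydrate digestion, 0 of 11 tested were higher and 10 lower (0 and 10 adjusted over the list alone, median -3.76, camera adjusted p = 1.11e-06, adjusted p = 0.238 with an estimated correlation). Of its genes, the fructose transporter gene Slc2a5 was at -5.58. For xenobiotic and retinoid metabolism, 0 of 23 tested were higher and 16 lower (0 and 17 adjusted over the list alone, median -2.80, camera adjusted p = 6.33e-09, adjusted p = 0.238 with an estimated correlation). Within it, Ugt1a1 was at -5.03. For MHC class II presentation, 0 of 7 tested were higher and 7 lower (0 and 7 adjusted over the list alone, median -3.44, camera adjusted p = 3.12e-05, adjusted p = 0.238 with an estimated correlation). Members include H2-Aa at -6.01. For interferon-stimulated genes, 1 of 18 tested were higher and 12 lower (1 and 13 adjusted over the list alone, median -1.66, camera adjusted p = 1.55e-07, adjusted p = 0.0537 with an estimated correlation). In this list, Isg15 was at -3.98. For ribosomal proteins, 40 of 40 tested were higher and 0 lower (40 and 0 adjusted over the list alone, median 2.06, camera adjusted p = 4.26e-17, adjusted p = 0.18 with an estimated correlation). Of its genes, Rpl3 was at 3.97 and Rpl13 at 3.23. For mitochondrially encoded transcripts, 0 of 13 tested were higher and 12 lower (0 and 13 adjusted over the list alone, median -2.12, camera adjusted p = 6.33e-09, adjusted p = 0.212 with an estimated correlation). Within it, mt-Co1 was at -2.70 and mt-Nd4 at -2.30. For cholesterol biosynthesis, 15 of 20 tested were higher and 0 lower (17 and 0 adjusted over the list alone, median 2.31, camera adjusted p = 6.72e-06, adjusted p = 0.158 with an estimated correlation). Members include Sqle at 3.27 and Fdps at 3.13. For the unfolded protein response, 14 of 20 tested were higher and 0 lower (14 and 1 adjusted over the list alone, median 1.39, camera adjusted p = 0.000169, adjusted p = 0.254 with an estimated correlation). In this list, Pdia6 was at 3.18.

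The limma interaction test with Benjamini-Hochberg adjustment called 3792 genes positive and 2258 negative, of which 2931 and 1674 had a size of at least 1 log2 unit. The counts were 5217 and 3422 without villus epi replicate 2, and 6032 calls were shared. The median over all genes was 0.21 as deposited and -0.02 with median-ratio scaling, which moved the positive share of calls from 62.7% to 50.8%. No list call of this contrast held with an estimated correlation, and the nearest was that of interferon-stimulated genes (adjusted p = 0.0537). With a pseudocount of 5, 4 of 37 named called genes moved by over 1.5 times and kept their calls, such as Tph1 (-1.42) and Ucn3 (-1.78).

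**Figure D4:**
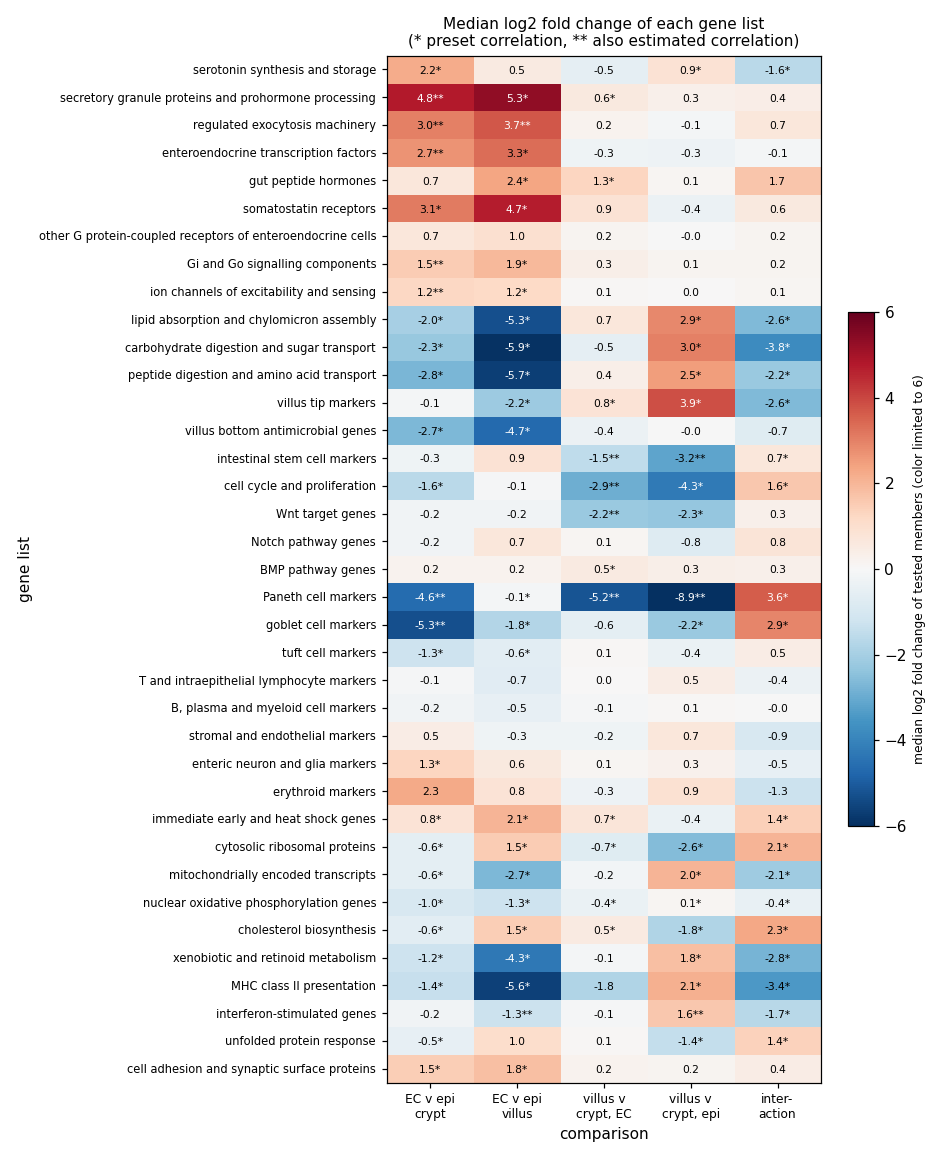
The columns are the 5 comparisons and each line is 1 gene list, with the median log2 fold change of its tested members as number and color, limited to 6. Single asterisks mark lists called by camera with the preset correlation, and double asterisks those also called with an estimated correlation, as for secretory granules in the crypt (median 4.77) and Paneth markers between villus epi and crypt epi (-8.90).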

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

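Chosen only after the results were seen were the counts over other splits, the tests of immune RNA, of the number of molecules and of another label for villus epi replicate 2, both tests of Paneth transcripts, and those of scaling, while the tests of GC content and length were written before. Other splits of libraries were run for each count. For EC against epi in the crypt, 1 of 35 splits of the 8 libraries, the real one, called as many genes (6088, highest other 1). In the villus it was 1 of 35 (8770, highest other 2089). For villus against crypt it was 1 of 35 in EC (3736, highest other 5) and 1 of 35 in epi (7755, highest other 1825). For the interaction it was 1 of 100 drawn splits with site exchanged within each cell type (6050, highest other 4906). The drawn splits still called many genes and cannot exclude chance. The others argue against it at a share under 0.05.

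Villus epi replicate 2 stood apart from its group, with 6451 genes over 1 log2 unit from the mean of the other 3, such as Actb at 53214 against 1426 to 1993 and Apob at 53.7 against 1175 to 1524 (genes chosen after their values were seen). GC content and length explained 9.34% of the variance of its deviation (0.342% to 0.791% in the other 3). This share argues against them as the whole cause, not as a part. The same holds for RNA from immune, stromal or glial cells. Markers (also chosen after) such as Col1a2 (2.27 against 0.995 to 1.58) and Cd3e (0.663 against 0.412 to 0.751) stayed low. Dcn (130.3 against 0.197 to 1.46) and Ptprc (24.6 against 1.06 to 1.69) rose, and 1 of 60 was at 100 or more, as in replicate 1. Amplification from fewer molecules stays open, as genes at 1 or more (12651 against 11318 to 11584) do not measure it. The label of another of the 4 groups is argued against by a mean correlation across genes of 0.812 with its own group and 0.676 at most with another. A sample from outside the 4 groups or a fault in preparing that library may stay open, and no biological explanation was tested.

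Paneth transcripts were present in crypt EC libraries, which the sort for CFP should free of Paneth cells. The 10 Paneth markers with at least 1000 in crypt epi stood at 1.70% to 4.36% of that level, and 90% of them lay within 1.5 times of the median of 3.80%, with Lyz1 at 3.73%, Defa24 at 4.00% and Itln1 at 3.58%. Carry-over of crypt epi RNA in its own proportions is argued against, since 5 of 8 abundant goblet markers, such as Clca1 (0.740%) and Zg16 (1.02%), lay more than 1.5 times under that median. Carry-over of Paneth RNA or cells could give such an even ratio, as a hypothesis, while expression of these genes by crypt EC cells was not tested and stays open.

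Ribosomal protein transcripts were lower and mitochondrially encoded ones higher in villus epi than in crypt epi. With the trend on GC content and length removed, the median log2 fold changes were -2.28 (before -2.61, SD of members 0.79) and 2.09 (before 2.03, SD of members 0.53), which argues against that trend as the whole cause. With median-ratio scaling they were -2.23 and 2.42, too small a shift to test the scaling. A difference between villus and crypt cells may account for it, as a hypothesis, and RNA quality was not tested.

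For 370 pairs of a named gene and a group, 59 had 1 library far from the other 3, with a gap to the nearest of them above the 95% value of Dixon for 4 values, and chance gives about 1 in 20. Crypt EC replicate 1 was that library 26 times, crypt epi replicate 3 14 times and villus epi replicate 2 9 times. The values that follow are those of the library against the range of the other 3.

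Crypt EC replicate 1 was low in Afp (619.8 against 1634 to 1674), Ucn3 (504 against 784 to 835), Chgb (27308 against 30109 to 30568), Slc18a1 (697 against 856 to 874), Snap25 (173 against 283 to 305), Sstr1 (127 against 181 to 192) and Glp1r (3.59 against 42.9 to 50.9). It was also low in Id1 (42.5 against 156 to 178), Id3 (130.5 against 403 to 449), Nt5e (11.3 against 120.2 to 132), Scg3 (53.3 against 82.2 to 84.1), Apoc3 (83.3 against 157 to 165), Sqle (63.2 against 87.8 to 91.3), Agr2 (248 against 925 to 1056) and Clps (144 against 218 to 227). Further low values were those of Nr4a1 (28.4 against 57.0 to 59.5), Dusp1 (289 against 932 to 969), Ern2 (5.46 against 14.3 to 15.9) and Hmgcs1 (68.6 against 113 to 118). The same library was high in Tac1 (6331 against 4335 to 4557), Sst (5.33 against 0 to 0.182), Gcg (35.2 against 0 to 0.260), Olfm4 (1337 against 787 to 861), H2-Aa (194 against 24.6 to 28.0), H2-DMa (23.6 against 7.46 to 10) and Rpl12 (9.93 against 7.38 to 7.67). Its mean correlation across genes with its group was 0.971 against 0.982 to 0.983. Crypt EC replicate 4 was high in Ptprc (1.09 against 0.441 to 0.544).

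Crypt epi replicate 3 was high in Tac1 (19.6 against 4.31 to 5.31), Reg3g (5156 against 2224 to 2542), H2-Ab1 (893 against 293 to 306), Cd74 (1859 against 490.1 to 546), H2-Aa (476 against 112 to 122) and H2-DMa (95.6 against 37.5 to 44.1). It was low in Tph1 (0.733 against 1.76 to 1.95), Fabp1 (1224 against 3840.3 to 4174), Apoc3 (83.9 against 209.8 to 227), Apoa1 (428 against 1869.8 to 2039), Selenop (84.7 against 197 to 216), Cyp3a11 (17.0 against 91.0 to 92.2), Slc15a1 (2.29 against 6.85 to 7.13) and Cyp3a25 (26.7 against 89.6 to 91.0).

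Villus epi replicate 2 was low in Maoa (152 against 553 to 597), Apoa4 (3364 against 12536 to 14270.5), Pdia6 (30.5 against 41.8 to 43.6) and Selenop (6859.6 against 12503 to 13109). It was high in Alpi (7739 against 3599 to 3783), Slc15a1 (758 against 91.7 to 142), Lgr5 (4.24 against 0.745 to 1.10), Spink4 (6631 against 901 to 1655) and Slc18a2 (21.1 against 1.67 to 2.77). Its summed value was 1190720.0 against 1390690.0 to 1415120.0 and its mean correlation across genes 0.812 against 0.923 to 0.926. Villus epi replicate 1 was high in Agr2 (749 against 487 to 520.5) and villus epi replicate 4 in Sst (85.1 against 0 to 1.68). Villus EC replicate 3 was high in Sst (58.8 against 0 to 2.43), Rpl3 (69.3 against 53.9 to 56.3), mt-Nd4 (458 against 418 to 423), Lgr5 (1.04 against 0.686 to 0.739) and Neurog3 (0.0592 against 0), and villus EC replicate 4 in Trpa1 (193 against 138 to 141) and Slc18a2 (9.80 against 4.65 to 5.43).

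For 37 named genes the EC difference itself differed between villus and crypt by the limma interaction test. Positive values, in log2 units, were those of Gcg (7.34), Habp2 (6.75), Sst (6.55), Agr2 (6.37), Clps (6.18), Pyy (5.93), Lyz1 (4.63), Plk1 (4.05), Rpl3 (3.97), Glp1r (3.57), Sqle (3.27), Rpl13 (3.23), Pdia6 (3.18), Fdps (3.13), Sct (2.59), Sstr2 (1.90), Mki67 (1.70) and Sstr5 (1.31). Negative values were those of Igfbp2 (-7.63), Mbl2 (-7.40), H2-Aa (-6.01), Slc2a5 (-5.58), Apoc3 (-5.23), Ugt1a1 (-5.03), Slc18a2 (-4.66), Isg15 (-3.98), Apoa4 (-3.78), Vim (-3.56), Ddc (-3.06), Tac1 (-2.80), Ucn3 (-2.76), mt-Co1 (-2.70), Tph1 (-2.67), Chga (-2.62), mt-Nd4 (-2.30), Chgb (-1.72) and Slc18a1 (-0.78).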

How the results depend on the processing

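The runs without villus epi replicate 2 and with median-ratio scaling together, and those of the lists without each library, were chosen after the data were seen. Over 248 of 268 alternative counts of genes called, the count lay within 1.5 times of that reported, 17 were larger and 3 smaller. Of 6560 alternative values of 245 named gene results, 6518 stayed on the same side of the threshold, 13 gained a call, 29 lost it and 0 reversed. Of 2256 alternative values of 94 list results, 2152 stayed on the same side, 17 gained a call, 86 lost it and 1 reversed. Of the 86, 61 were lost with an estimated correlation. The reversed one was the list of B, plasma and myeloid cell markers in the crypt, where fry gave the opposite direction (median -0.21, adjusted p = 5.55e-07). With a mean value of at least 5, which tests fewer genes, 2055 genes were higher and 2304 lower in crypt EC than crypt epi, so that more were lower. With only the 2 groups compared, 4406 genes were lower in that comparison, and 2779 and 3891 were higher and lower in villus EC than crypt EC. With library weights these were 5177 higher and 4751 lower in crypt EC than crypt epi, 3086 and 4169 in villus EC than crypt EC, and 3549 negative interactions. Without villus epi replicate 2 and with median-ratio scaling, 4435 genes were lower in crypt EC and 4678 in villus EC than in epi, 3200 higher in villus EC than crypt EC, 5016 higher in villus epi than crypt epi, and 4427 interactions negative. Leaving out 1 library gave 2931 to 4726 genes higher and 2426 to 4294 lower in crypt EC than crypt epi, 5410 to 6762 and 2828 to 3756 in villus EC than villus epi, 1166 to 2708 and 1822 to 3857 in villus EC than crypt EC, 2452 to 3627 and 4639 to 5831 in villus epi than crypt epi, and 3473 to 5217 and 2065 to 3422 in the interaction. The highest of each came without villus epi replicate 2. For the crypt comparison and that within EC cells, villus epi libraries enter only through the shared spread, so that spread accounts for those 2, and for the others the cause was not tested. The depth of the libraries is unknown, so what it limits cannot be given.

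A replicate block was not used for the values reported, because the title and library numbers disagree and no label says that a number is a mouse. Across genes, the deviations of libraries sharing a library number had a median r of -0.097 over 10 pairs (-0.268 to 0.139), and those sharing a title number -0.035 over 24 pairs (-0.268 to 0.170). With a block by library number, 609 genes were higher and 1232 lower in villus EC than crypt EC, and the cause was not tested. That block ended 15 named gene calls. Within EC cells they were Sstr5 (adjusted p = 0.0978), Sstr3 (0.065), Cck, Id1, Id3, Atoh1, Apoa4, Nt5e, Scg3, Dusp1 and Atf3. In the crypt they were Dusp1 and Ddit3, and in the interaction Sct and Sstr5 (0.0912). A block by title number ended 1, Atf3 within EC cells (adjusted p = 0.0546). Lists that lost their call by library number were gut hormones in the villus (0.121) and within EC cells (0.183), and serotonin between villus epi and crypt epi (0.0864). By title number it was gut hormones within EC cells (0.0516). The erythroid list in the crypt gained a call by library (0.0373) and title number (0.0276).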

Other observations

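Stress and housekeeping groups, picked after the results were seen, also differed between crypt EC and crypt epi. For immediate early and heat shock genes, 9 of 20 tested were higher and 0 lower (11 and 0 adjusted over the list alone, median 0.84, camera adjusted p = 0.0145, adjusted p = 0.445 with an estimated correlation). Members include Nr4a1 at 2.11 and Dusp1, a phosphatase gene, at 1.36 (adjusted p = 0.00435). For cytosolic ribosomal proteins, 0 of 40 tested were higher and 29 lower (0 and 29 adjusted over the list alone, median -0.58, camera adjusted p = 1.62e-07, adjusted p = 0.259 with an estimated correlation). In this list, Rpl12 was at -1.23. For MHC class II presentation, 0 of 7 tested were higher and 5 lower (0 and 6 adjusted over the list alone, median -1.37, camera adjusted p = 0.0233, adjusted p = 0.445 with an estimated correlation). Of its genes, H2-DMa was at -2.13, and the call of the list ended without crypt epi replicate 3 (adjusted p = 0.0648) and without villus epi replicate 2 (adjusted p = 0.0744). For the unfolded protein response, 1 of 20 tested were higher and 9 lower (1 and 9 adjusted over the list alone, median -0.48, camera adjusted p = 0.00712, adjusted p = 0.38 with an estimated correlation). Ern2, a sensor of misfolded proteins of goblet cells, was at 12.8 against 112 (log2 fold change -3.13, adjusted p = 5.99e-07), while Ddit3 rose by 1.16, a call that ended without crypt epi replicate 3 (adjusted p = 0.0519).

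Between villus EC and crypt EC, some cholesterol and stress genes were higher, though most members of both lists did not pass the test. For cholesterol biosynthesis, 4 of 20 tested were higher and 0 lower (4 and 0 adjusted over the list alone, median 0.54, camera adjusted p = 0.00868, adjusted p = 0.427 with an estimated correlation), with Hmgcs1 at 239 against 104 (log2 fold change 1.18, adjusted p = 0.00129) and Fdps at 0.85. For immediate early and heat shock genes, 5 of 20 tested were higher and 0 lower (5 and 0 adjusted over the list alone, median 0.73, camera adjusted p = 0.000901, adjusted p = 0.469 with an estimated correlation). Within it, Dusp1 was at 1802 against 786 (log2 fold change 1.34, adjusted p = 0.00859). Atf3 was also higher (log2 fold change 1.41, adjusted p = 0.0335), but that call was not stable, as it ended when any of 5 libraries was left out (adjusted p = 0.0501 to 0.123).

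A hypothesis is that crypt EC replicate 1 holds cells from lower along the crypt to villus axis than the other crypt EC libraries, and its test was written before the result was seen. Of the 1166 genes higher in villus EC when that library is left out, 75.7% were lower in it than in the mean of the other 3, and of the 1822 genes lower in villus EC, 73.7% were higher in it. The values may thus fit the hypothesis, though the same measure of the other 3 libraries has that library in its reference and so gives no value for an unchanged one, the genes are not independent, the comparison was made on the data that raised it, and other differences of that library were not excluded.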
